A study of Homo sapiens with 9 samples.

How the data were processed

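RNA was measured in 9 libraries of cultured human myotubes, 1 control library and 2 PAD libraries for each of the oxygen conditions N, NH and NHH. According to the submitters' processing notes, reads were aligned with HISAT2 to hg38 and compared with Cuffdiff, without versions, annotation release or settings. The deposited tables give, for each gene, the authors' FPKM of 2 groups, scaled by the authors within each table. They also give the authors' log2 fold change, p value and q value (adjusted for the false discovery rate) and a test status. The table of the control comparisons and those of PAD NH and PAD NHH against control N list 65712 rows, and the table of PAD N against control N holds the 11990 rows that were tested. Values per library and raw counts were not used here, so no test across samples was run, no paired analysis by donor was possible and the authors' p and q were used as deposited, at a threshold of q under 0.05 among rows with status OK. The smallest p in the tables was 5e-05. Total counts per library were not used here; the implied depth of the control libraries comes from the commonest product of FPKM and transcript length among low values of genes with a single annotated transcript of at least 1.5 kb, and it states no precision for single values.

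Control N appears in every table, and its values differ between tables by a near-constant factor. To set groups of separate tables side by side, each PAD group was divided by the median ratio of control N in its table to control N in the control table, over genes with more than 1 FPKM in the latter, which was 1.01 for PAD N, 0.956 for PAD NH and 0.997 for PAD NHH. FPKM of a symbol with several rows were summed, for PAD N over the tested rows only. Of 59405 symbols, 2939 had a row on an alternate or patch scaffold beside another row. No fold is printed for genes listed at exactly 0 in a group; in the counts and medians of lists they rank beyond every finite fold. Rows with another status than OK were not tested, among them COL1A1 and FN1 in PAD NH against control N (status HIDATA, with a listed 0 that is not a measured level). Transcript lengths and gene positions came from GENCODE 29 on GRCh38, taking the longest annotated transcript, and the trend with length was computed over genes without scaffold copies and with a mean of at least 1 FPKM. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.

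Before the data were examined, 36 gene lists were fixed, 28 for themes and 8 for markers of cell types. The themes were HIF targets in glycolysis, HIF targets in signalling, pH and angiogenesis, NRF2 targets, metallothioneins, mitochondrial DNA genes, respiratory chain, mitochondrial biogenesis, fatty acid oxidation, cholesterol synthesis, myogenic regulators, sarcomere, calcium handling, muscle atrophy, autophagy, cell cycle, p53 targets, NF-kB targets, interferon-stimulated genes, complement, unfolded protein response, heat shock, immediate early genes, collagens and crosslinking, matrix remodelling, TGF-beta targets, insulin and IGF signalling, histones and ribosomal proteins. The marker lists were for fibroblasts, adipocytes, smooth muscle, endothelium, immune cells, Schwann cells, myoblasts and epithelium. A list with at least 5 measured members, which held for 31 lists, was described by its median log2 fold and the percentile of that median among 10000 random lists of the same size matched on deciles of expression (seed 1). Measured members are those with a tested row. A list was said to stand apart when its 2-sided share among the random lists, adjusted by Benjamini-Hochberg over the 31 lists of a comparison, was under 0.05. That share describes genes against other genes within these libraries and not samples. For the deposited comparisons, members past the authors' q were counted, and also members past 0.05 when the authors' p was adjusted over the list alone.

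Genes were named by a rule fixed before the data were examined. For each comparison it takes the 6 highest and the 6 lowest log2 folds among genes past q with at least 5 FPKM in the higher and 0.1 FPKM in the lower group, and from each list up to 2 members past q with at least 1 FPKM in the higher group, or the most expressed member where none passed. Other list members that are named with their levels were chosen after their values were seen. Genes on the Y chromosome, in the pseudoautosomal regions and in the HLA family, XIST, and genes with common deletions or strong genotype effects were left out, since they can carry details of a donor.

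Comparisons between PAD groups, and between PAD and control within a cycle, used the rescaled values and gave counts of genes at least 2-fold apart with at least 1 FPKM in the higher group. The PAD response to cycling was set against the control response by Pearson's correlation across genes, with an SD over 200 bootstrap draws of genes. The list test was tested on simulated data in which folds were permuted over genes and 200 genes of 10 lists were then shifted. It used 2000 random lists in place of 10000. In control NH against control N it found 8, 10 and 10 of the 10 lists at added log2 folds of 0.5, 1 and 2, and called 0, 1 and 0 of 40 unchanged lists. In PAD N against control N it found 4, 10 and 10, and called 0, 0 and 0. The permutation removed the trend with transcript length and any correlation between members of a list. The calls of unchanged lists therefore do not carry over to the real lists.

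Alternatives chosen before the data were examined were a threshold of q under 0.01, a minimum log2 fold of 1, minima of 1 and 5 FPKM, centring on the median, a pseudocount of 1 FPKM and random lists not matched on expression. Alternatives chosen after seeing the data were leaving out genes with scaffold copies, using the row on the primary chromosome or the sum over copies, removing the trend with length and matching random lists on length too. The contrasts of PAD with control within the same cycle were also chosen after seeing the data. Mitochondrial DNA genes were left out of list tests because none was tested by the authors.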

Results

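Primary human skeletal muscle cells were differentiated for 4 days into myotubes, the multinucleate muscle fibres that form in culture, and polyA RNA was sequenced from 9 libraries. The cells came from 1 healthy control donor and from 2 donors with peripheral artery disease (PAD), a narrowing of the arteries that supply the limbs. Cells were kept at 20% oxygen (N), cycled through 90 min of normoxia and 90 min at 1% oxygen (NH), or cycled through 90 min of normoxia, 60 min at 1% oxygen and 30 min of hyperoxia at 30% oxygen (NHH). Each condition had 1 control library and 2 PAD libraries. The deposited files held 4 tables with 6 comparisons of group values in FPKM (fragments normalized for transcript length and library size), and 5 of the 6 comparisons used the control N library.

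Library totals were not used here. For the 3 control libraries, the commonest low product of FPKM and transcript length in kb was 0.116 in control N and 0.133 in each of control NH and control NHH, on a histogram with steps of 7.15%, and the inverse of that product is a rough library size (8.61 in control N, in units of 1e6 fragments). No control condition had a replicate, and the PAD values were the authors' values over the 2 PAD libraries, so no spread between replicates is given for any value. The authors' q values therefore rest on a model of variance, and a difference between control and PAD is a difference from 1 donor. FPKM levels of PAD and cycled groups set side by side come from separately normalized tables and were rescaled to the control table.

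The comparison of PAD N with control N addressed how myotubes of patients and of a healthy donor differ at constant oxygen. Genes of differentiated muscle were far higher in the PAD myotubes. MYBPC1, a myosin-binding protein of the sarcomere, stood at 0.226 FPKM in control N and 70.6 FPKM in PAD N, and MYL2, a myosin light chain of slow muscle and heart, stood at 4.23 and 544 FPKM. CKM, the muscle creatine kinase, stood at 8.79 and 494 FPKM. MYOG, the transcription factor that drives terminal muscle differentiation, stood at 9.38 and 201 FPKM, and its partner MEF2C stood at 254 FPKM in PAD N.

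In the authors' deposited table, MYBPC1 (ENSG00000196091.15) rose in PAD N against control N by 8.29 on the log2 scale, which is 313-fold, with q = 0.0102. This fold starts from a level under 1 FPKM in the single control N library, so its size is uncertain. MYL2 (ENSG00000111245.17) rose by 7.01, CKM (ENSG00000104879.5) by 5.81 and MYOG (ENSG00000122180.5) by 4.42 in the authors' deposited table, each with q = 0.0102. MEF2C rose by 4.82 with q = 0.0180 in the same deposited table. On GRCh38, MYBPC1 lies on the plus strand of chromosome 12 from 101568353 to 101686018, and MYL2 on the minus strand of chromosome 12 from 110910819 to 110920722. CKM lies on the minus strand of chromosome 19 from 45306414 to 45322977, and MYOG on the minus strand of chromosome 1 from 203083132 to 203086036. FGFR4, a growth factor receptor, rose by 4.84 with q = 0.0102 in the authors' deposited table. CASQ2, a calcium store protein of the sarcoplasmic reticulum, rose by 4.30 with q = 0.0102, and RBFOX1, a splicing factor of muscle and brain, by 4.68 with q = 0.0180 in the authors' deposited table. COX6A2, the muscle form of a cytochrome c oxidase subunit, rose by 4.79 with q = 0.0180 in that deposited table. SGCA, a member of the dystrophin complex, rose by 3.72 with q = 0.0497, and the protease CTSH by 3.38 with q = 0.0431 in the authors' deposited table.

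**Figure D1:**
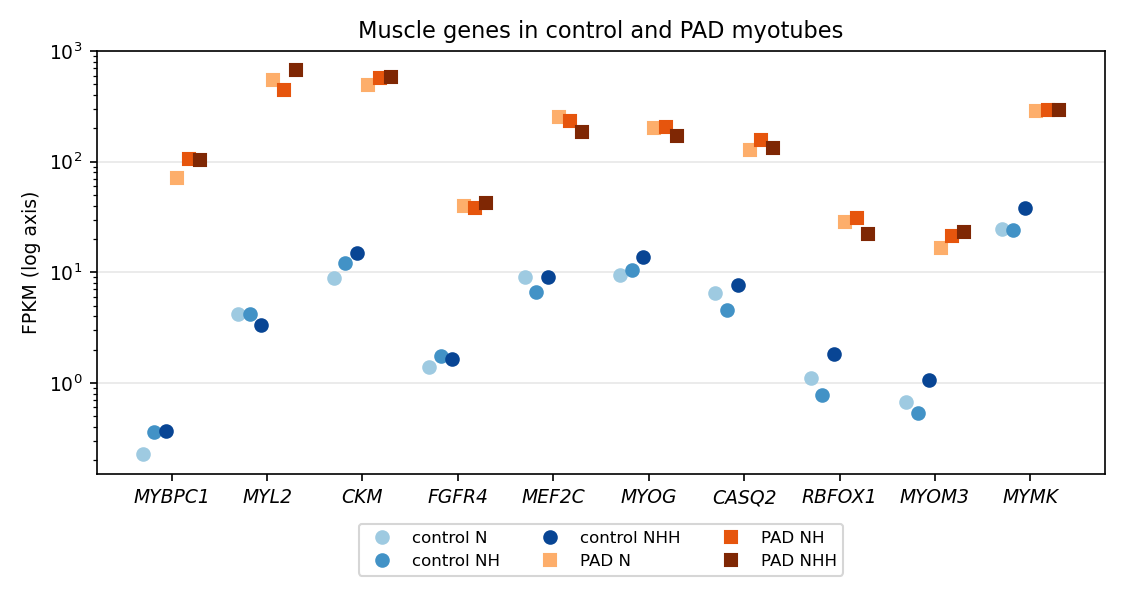
FPKM on a log axis of 10 muscle genes in the 6 groups, with 1 point per group (circles, 1 control library each; squares, the authors' value over the 2 PAD libraries), all on the scale of the control table. For each gene the 3 PAD values lie above the 3 control values, as for MYL2 with 447 to 675 FPKM in PAD and 3.31 to 4.23 FPKM in control.

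The muscle lists moved as groups in PAD N against control N. All 37 measured members of the sarcomere list were higher, with a median log2 fold of 3.99. Of them, 6 passed q over all genes in the authors' deposited table, namely CKM, MYBPC1, MYL2, MYOM3, TNNC2 and, in its row on an extra scaffold, TNNT3, and 19 passed when adjusted over the list alone. All 17 members of the calcium handling list were higher (median 4.20), with CASQ2 past q and 10 members when adjusted over the list alone. All 13 measured myogenic regulators and fusion genes were higher (median 3.40), with MEF2C and MYOG past q and 7 when adjusted over the list alone. Markers of myoblasts and satellite cells, the muscle precursors, were higher for 7 of 8 members (median 3.92). None of them passed q over all genes and 4 did when adjusted over the list alone. Desmin (DES), the muscle intermediate filament, stood at 113 FPKM in control N and 2453 FPKM in PAD N without passing q. These 4 medians exceeded every one of 10000 random lists matched on expression. The myoblast list shares members with the sarcomere list and the myogenic regulators, so the medians are not separate results.

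Beyond the muscle lists, 19 of 20 cholesterol synthesis genes were lower in PAD N than in control N (median log2 fold -1.15). FDPS, which makes farnesyl pyrophosphate, stood at 765 FPKM in control N and 441 FPKM in PAD N, and LSS, the lanosterol synthase, at 224 and 55.1 FPKM. Collagens and crosslinking enzymes were lower for 18 of 22 members (median -0.79). Nuclear-encoded respiratory chain subunits were higher for 32 of 33 members (median 0.75), HIF glycolysis targets for 17 of 21 (median 0.66), metallothioneins for 6 of 6 (median 1.36), and NF-kB targets for 12 of 15 (median 1.08). Heat shock genes (median 0.79) and epithelial markers (median 1.75) also stood above the random lists. No member of these lists passed q except HSPB8, a small heat shock protein of muscle, which rose by 3.35 with q = 0.0368 in the authors' deposited table. MX1, an interferon-induced GTPase, fell by 3.51 with q = 0.0102, and RUNX1T1, a transcriptional corepressor, fell by 2.51 with q = 0.0180 in the authors' deposited table. SH3TC1 rose by 3.38 with q = 0.0248 in the authors' deposited table. Against the same control N library, MX1 was also lower in control NH, and in control NHH RUNX1T1 was lower and SH3TC1 higher. For these genes a difference of PAD cannot be told apart from a property of that library. The interferon-stimulated list as a whole lay at percentile 2.02 of the random lists (median -0.47), which did not pass the adjustment over 31 lists.

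The authors' deposited table tested 11990 genes in PAD N against control N and 29 passed q, 21 of them higher and 8 lower in PAD N. None of the 29 was listed at 0 in 1 of the groups. Among calls against control N, 54 of 78 in PAD NH and 45 of 75 in PAD NHH were, so these counts are not like for like. Of the 29, 8 were genes that are also listed on extra scaffolds of the assembly, among them POLR3E, HNRNPR and TAF15. Log2 folds also followed transcript length in this comparison (Spearman -0.288 across genes, which are not independent replicates), with medians of 0.54 for transcripts under 1 kb and -0.23 for those over 8 kb. At q under 0.01 no gene passed, since the smallest q in this table was 0.0102. The smallest p was 5e-05 here as in the control comparisons, so this does not show a weaker difference.

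In the comparison of control NH with control N, which addressed the response of healthy myotubes to cycles of hypoxia, glycolysis targets of the hypoxia-inducible factor HIF were higher as a group. PFKFB3, which makes the strongest activator of glycolytic phosphofructokinase, stood at 8.48 FPKM in control N and 31.2 FPKM in control NH. ANGPTL4, a secreted inhibitor of lipoprotein lipase, stood at 25.9 and 87.3 FPKM, and DDIT4, an inhibitor of mTORC1 signalling, at 74.7 and 173 FPKM. Each of the 21 HIF glycolysis targets was higher in control NH, with GAPDH at 2233 and 4469 FPKM. The interferon-induced MX1 and ABCC9, a subunit of potassium channels in vascular smooth muscle, were lower. MX1 was also lower in PAD N than in this control N library, without cycling. A response of MX1 to cycling therefore cannot be told apart from a property of that library.

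In the authors' deposited table, PFKFB3 (ENSG00000170525.21) rose in control NH against control N by 1.88 on the log2 scale with q = 0.0209. ANGPTL4 (ENSG00000167772.12) rose by 1.75 and DDIT4 (ENSG00000168209.6) by 1.21 in the authors' deposited table, each with q = 0.00861. On GRCh38, PFKFB3 lies on the plus strand of chromosome 10 from 6144934 to 6254644, ANGPTL4 on the plus strand of chromosome 19 from 8363289 to 8374373, and DDIT4 on the plus strand of chromosome 10 from 72273920 to 72276036. MX1 fell by 2.15 and ABCC9 by 1.80 in the authors' deposited table, each with q = 0.00861.

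The HIF glycolysis list had a median log2 fold of 0.77 in control NH against control N, above every random list, with 1 member past q in the authors' deposited table and 1 when adjusted over the list alone. The list of HIF targets in signalling, pH and angiogenesis had a median of 0.23, at percentile 79.3, which did not stand apart, and ANGPTL4 and DDIT4 were its members past q, with 5 members past it when adjusted over the list alone. All 29 cytosolic ribosomal proteins were higher (median 0.67), with RPS12 at 4631 and 6949 FPKM; none passed q over all genes and 5 did when adjusted over the list alone. Respiratory chain subunits were higher for 31 of 33 members (median 0.45), metallothioneins for 8 of 8 (median 0.79), cell cycle genes for 16 of 22 (median 0.36) and epithelial markers for 5 of 5 (median 0.82). Among p53 targets, 12 of 16 were lower (median -0.39), with the p53 antagonist MDM2 at 49.3 and 21.1 FPKM, and 17 of 22 collagen and crosslinking genes were lower (median -0.18). Apart from NDUFS1, which is also listed on a scaffold, no member of these 7 lists passed q.

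Of 11702 genes tested in control NH against control N, 120 passed q in the authors' deposited table, 55 higher and 65 lower. Genes with a second copy on an extra scaffold made up 3.78% of the tested genes and 60.8% of those past q (73 of 120). Among them was ID3, an inhibitor of myogenic transcription factors, which rose by 5.49 with q = 0.00861 in the authors' deposited table. DDT rose by 5.25 and TAF15 fell by 4.95 in the authors' deposited table, each with q = 0.00861. Without such genes 47 passed q, 19 of them higher. Copies listed under another symbol were not looked for, so these 47 can still hold genes with such copies. Among those 47, U2AF1, a splicing factor subunit, rose by 4.02 and LYSMD3 fell by 3.94 in the authors' deposited table, each with q = 0.00861.

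Log2 folds in control NH against control N also followed transcript length (Spearman -0.458 across genes), with medians of 0.48 for transcripts under 1 kb and -0.44 for those over 8 kb. Among called genes without scaffold copies, the median longest transcript was 2.56 kb for the higher and 7.46 kb for the lower ones, against 3.58 kb for all tested genes. When random lists were matched on length too, an alternative chosen after seeing the data, 3 of the 8 lists that stood apart did so, and these were the HIF glycolysis, ribosomal protein and p53 lists.

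**Figure D2:**
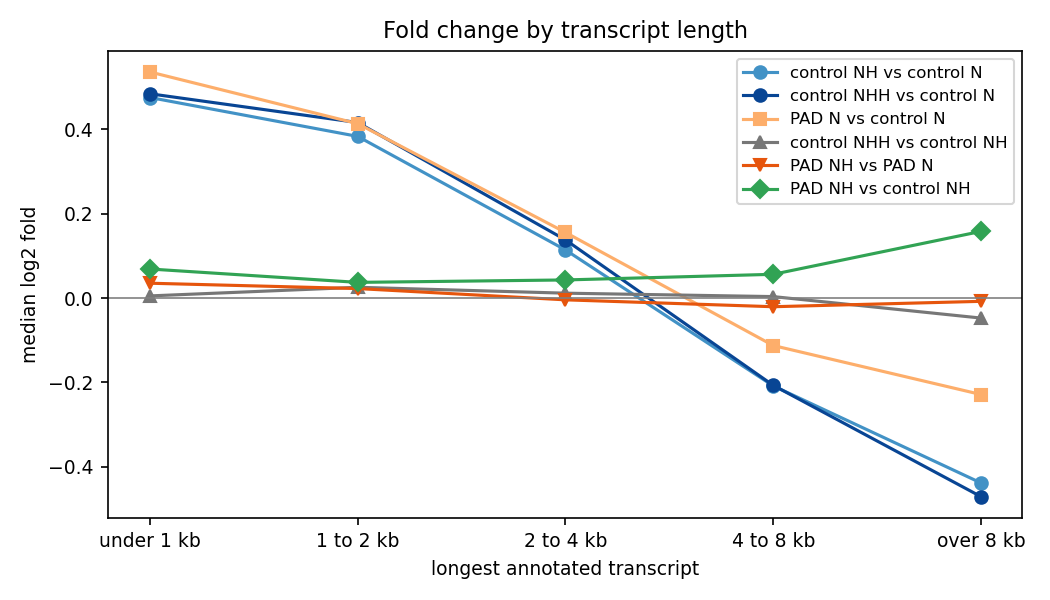
Median log2 fold (vertical axis) of genes without scaffold copies, by the length class of their longest annotated transcript (horizontal axis), for 6 comparisons. The 3 comparisons with control N fall from 0.48 to 0.54 under 1 kb to between -0.23 and -0.47 over 8 kb, while the 3 others lie between -0.05 and 0.16.

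In control NHH against control N, where hypoxia cycling and hyperoxia changed together, cell cycle and sarcomere genes were higher as groups. Of 23 measured cell cycle genes 19 were higher in control NHH (median log2 fold 0.68), with TOP2A, the topoisomerase of dividing cells, at 10.8 and 18.1 FPKM and PLK1, a mitotic kinase, at 4.49 and 11.0 FPKM. Of 33 sarcomere genes 26 were higher (median 0.46), with the embryonic myosin MYH3 at 86.4 and 140 FPKM and the cardiac actin ACTC1 at 529 and 805 FPKM. All 29 ribosomal proteins were higher (median 0.63), and 13 of 22 collagen and crosslinking genes were lower (median -0.21). KRT18, an intermediate filament keratin, rose by 1.45 with q = 0.00861 in the authors' deposited table.

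No member of the cell cycle or collagen list passed q in control NHH against control N. TNNT3, the fast muscle troponin T, rose by 3.66 with q = 0.00861 in the authors' deposited table, in its row on an extra scaffold, and 3 sarcomere genes passed when adjusted over the list alone. Of the ribosomal proteins, 0 passed q and 4 did when adjusted over the list alone. HIF glycolysis targets had a median of 0.44 at percentile 99.4, which did not pass the adjustment over the 31 lists, and myogenic regulators (0.51, percentile 99.5) and calcium handling genes (0.51, percentile 98.8) did not either. The HIF signalling list had a median of 0.05. ABCC9 fell by 1.77 with q = 0.00861, and RUNX1T1 fell by 2.15 with q = 0.0156 in the authors' deposited table. U2AF1 rose by 4.02 with q = 0.00861, and SH3TC1 rose by 2.79 with q = 0.0408 in the authors' deposited table. RUNX1T1 and SH3TC1 moved the same way in PAD N against that control N library, without cycling. For them a response to the cycle cannot be told apart from a property of that library. With random lists also matched on length, the sarcomere and collagen lists no longer stood apart and the HIF glycolysis list did.

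Of 11773 genes tested in control NHH against control N, 118 passed q in the authors' deposited table, 58 higher and 60 lower, and 57 of them (48.3%) had scaffold copies. Leaving these out, 61 passed q, 24 of them higher. The relation with transcript length was the same size as in control NH (Spearman -0.458), with a median length of 2.22 kb for the higher and 7.44 kb for the lower calls without copies.

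Control NHH and control NH were compared directly, which does not involve the control N library. The 2 cycles differ both in hyperoxia and in the time at 1% oxygen (60 min in NHH and 90 min in NH), and the number of cycles and the point of the cycle at which RNA was taken are not known here. HIF targets were lower and muscle genes higher in control NHH. PFKFB3 stood at 31.2 FPKM in control NH and 6.48 FPKM in control NHH, and 18 of 21 HIF glycolysis targets were lower (median log2 fold -0.25), as were 17 of 24 HIF signalling targets (median -0.24) and 7 of 8 metallothioneins (median -0.52). Sarcomere genes were higher for 30 of 33 members (median 0.50), with the myosin light chain MYLPF at 260 and 426 FPKM, and calcium handling genes for 11 of 13 (median 0.49). Myogenic regulators (median 0.41), myoblast markers (median 0.40), cell cycle genes (median 0.32) and collagen genes (median 0.12) were higher as well.

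In the authors' deposited table, PFKFB3 fell in control NHH against control NH by 2.27 with q = 0.00861, and it was the only member of these HIF lists past q. NIPA2, a magnesium transporter, fell by 4.23 with q = 0.00861 in the authors' deposited table. In the lists that stood apart, the other members past q were TNNT3, which rose by 4.34, and ID3, which fell by 4.55, each with q = 0.00861 in the authors' deposited table and each in a row on an extra scaffold. Of 11689 genes tested, 82 passed q, 36 higher and 46 lower, and 63 of them (76.8%) had scaffold copies. The correlation with transcript length was -0.0414 in this comparison.

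**Figure D3:**
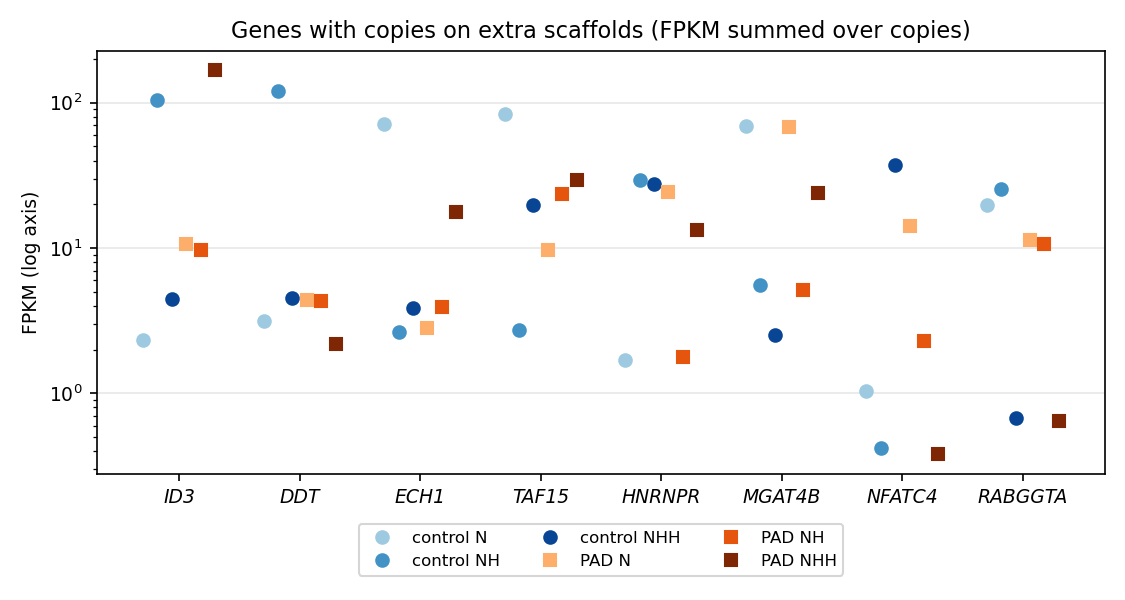
FPKM on a log axis, summed over the listed copies, of 8 genes that also have a copy on an extra scaffold, in the 6 groups (circles, 1 control library each; squares, the authors' value over the 2 PAD libraries). The order of the groups differs from gene to gene, as for ID3, at 105 FPKM in control NH and 168 FPKM in PAD NHH, and DDT, at 121 and 2.17 FPKM.

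PAD NH was compared with control N, so that donor and cycling changed together. The muscle genes were again higher in PAD, and HIF and inflammatory genes were higher as groups. MYBPC1 rose by 8.88 with q = 0.0109, and MYL1, the fast myosin light chain, rose by 5.92 with q = 0.0253 in the authors' deposited table. MYF6, a myogenic transcription factor, and the neutrophil chemokines CXCL6 and CXCL3 were listed at 0 in control N and stood at 4.12, 14.4 and 2.31 FPKM in PAD NH, and each passed q. No call in PAD N against control N was listed at 0 in a group, so the lack of such calls there does not show an effect of cycling. IL32, a proinflammatory cytokine, rose by 3.81 with q = 0.0320 in the authors' deposited table.

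All 37 sarcomere genes (median log2 fold 4.25), all 17 calcium handling genes (4.12), all 15 myogenic regulators (3.59) and 8 of 9 myoblast markers (3.59) were higher in PAD NH than in control N. MYBPC1, MYL1, MYOM2, MYOM3 and, in its row on an extra scaffold, TNNT3 passed q among the sarcomere genes and MYF6 among the myogenic regulators. MYOM2 also has a scaffold copy. Its row past q, on the primary chromosome, was listed at 0 in control N and stood at 4.66 FPKM in PAD NH. Its scaffold row, at 0.281 and 19.1 FPKM, was not among those past q. Adjusted over the list alone, 20 sarcomere, 10 calcium handling, 7 myogenic and 3 myoblast genes passed. HIF glycolysis targets were higher for 19 of 21 members (median 1.10), HIF signalling targets for 22 of 26 (median 1.02), NF-kB targets for 16 of 19 (median 1.98), matrix proteases and their inhibitors for 10 of 18 (median 0.80), ribosomal proteins for 29 of 29 (median 0.79), respiratory chain subunits for 30 of 33 (median 0.68) and epithelial markers for 6 of 6 (median 1.78). Cholesterol synthesis genes were lower for 19 of 20 (median -0.96) and interferon-stimulated genes for 10 of 15 (median -0.69). Apart from CXCL6 and CXCL3, no member of these 9 lists passed q. The measured members of a list differ between the PAD comparisons, so their medians are not over the same genes.

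Among single genes in PAD NH against control N, SAMHD1, a hydrolase of nucleotide triphosphates, fell by 4.50 with q = 0.0109 in the authors' deposited table. COL7A1, the collagen of anchoring fibrils, fell by 3.18 with q = 0.0109, and NEDD9, a focal adhesion scaffold protein, fell by 2.90 with q = 0.0253 in the authors' deposited table. PAPLN, an extracellular matrix protein, fell by 4.61 with q = 0.0320, while RBFOX1 rose by 4.80 and MYOM3 by 4.98, each with q = 0.0109, in the authors' deposited table. Of 12117 genes tested 78 passed q, 58 higher and 20 lower; 54 of the 78 were listed at 0 in 1 of the groups and 23 had scaffold copies. The correlation with transcript length was -0.276, and no gene passed q under 0.01, since the smallest q was 0.0109.

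In PAD NHH against control N donor and cycling also changed together, and muscle genes were higher in PAD. MYBPC1 rose by 8.83 with q = 0.0206, MYL2 by 7.32 with q = 0.0351 and COX6A2 by 4.87 with q = 0.0351 in the authors' deposited table. MYMK, the myomaker protein of myoblast fusion, rose by 3.57 and the neural cell adhesion molecule NCAM1 by 3.65, each with q = 0.0465 in the authors' deposited table. HSPB8 rose by 4.60 and the matrix protein TNC by 3.20, each with q = 0.0415 in the authors' deposited table. MYF6, CXCL6 and CXCL3, listed at 0 in control N, stood at 7.01, 9.55 and 1.46 FPKM in PAD NHH and passed q. As in PAD NH, these calls do not show an effect of cycling. IL32 rose by 3.78 with q = 0.0465 and RBFOX1 by 4.32 with q = 0.0127 in the authors' deposited table.

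All 38 sarcomere genes (median log2 fold 4.23), all 17 calcium handling genes (4.12), 14 of 15 myogenic regulators (3.65) and 7 of 8 myoblast markers (3.44) were higher in PAD NHH than in control N. MYBPC1, MYL2 and MYOM3 passed q among the sarcomere genes, and MYF6, MYMK, NCAM1 and, in its row on an extra scaffold, ID3 among the myogenic regulators. Adjusted over the list alone, 24 sarcomere, 9 calcium handling, 9 myogenic and 4 myoblast genes passed. Cell cycle genes were higher for 23 of 24 members (median 0.88), HIF glycolysis targets for 18 of 21 (1.09), HIF signalling targets for 20 of 26 (0.71), NF-kB targets for 12 of 17 (1.75), matrix proteases for 11 of 18 (0.94), metallothioneins for 6 of 6 (0.98), respiratory chain subunits for 31 of 33 (0.68), ribosomal proteins for 28 of 29 (0.60) and epithelial markers for 6 of 6 (2.26). Cholesterol synthesis genes were lower for 19 of 20 (-1.15), interferon-stimulated genes for 10 of 16 (-0.59) and collagen genes for 18 of 23 (-0.37). Of 11894 genes tested 75 passed q, 59 higher and 16 lower; 45 were listed at 0 in 1 of the groups and 22 had scaffold copies. The correlation with transcript length was -0.282, and no gene passed q under 0.01, since the smallest q was 0.0127.

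The response of PAD myotubes to cycling was read from the 3 PAD groups, for which no q was analysed here, so the values below are differences between rescaled tables without a test of single genes. In PAD NH against PAD N, HIF targets were higher. ANKRD37, a HIF target of unsettled function, stood at 73.1 FPKM in PAD N and 211 FPKM in PAD NH, VEGFA, the angiogenic growth factor, at 51.3 and 132 FPKM, and PDK1, which diverts pyruvate from the mitochondria, at 6.01 and 13.0 FPKM. HIF glycolysis targets were higher for 20 of 21 members (median log2 fold 0.57) and HIF signalling targets for 21 of 24 (median 0.60). Collagen and crosslinking genes were higher for 19 of 21 (median 0.51), with LOXL2 at 88.9 and 341 FPKM. Targets of the unfolded protein response and ATF4 were higher for 17 of 19 (median 0.55), with ASNS, the asparagine synthetase, at 90.4 and 243 FPKM.

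Matrix proteases (median 0.56), cell cycle genes (0.36), cholesterol synthesis (0.24), TGF-beta targets (0.24), ribosomal proteins (0.24) and sarcomere genes (0.16) also stood above the random lists in PAD NH against PAD N. Metallothioneins were lower for 6 of 6 members (median -1.09), with MT1X at 782 and 367 FPKM, heat shock genes for 9 of 10 (-0.23), and fibroblast markers had a median of -0.27. The correlation with transcript length was -0.0318. Of 11327 genes 463 were at least 2-fold higher and 455 at least 2-fold lower in PAD NH, and the total of 918 became 497 with a minimum of 5 FPKM in the higher group.

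In PAD NHH against PAD N, cell cycle genes were higher for 24 of 24 members (median log2 fold 0.88), with PLK1 at 5.21 and 14.4 FPKM and CDK1, the mitotic cyclin-dependent kinase, at 4.90 and 12.5 FPKM. HIF glycolysis targets were higher for 20 of 21 (median 0.36) and HIF signalling targets for 20 of 24 (median 0.43). Matrix proteases (0.25), collagen genes (0.21) and sarcomere genes (0.20) stood above the random lists, and metallothioneins (-0.48) and NRF2 targets (-0.15) below them. Of 11255 genes 318 were at least 2-fold higher and 277 at least 2-fold lower, a total of 595 that became 245 with a minimum of 5 FPKM in the higher group.

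In PAD NHH against PAD NH, which differ in hyperoxia and in the time at 1% oxygen, cell cycle genes were higher for 22 of 24 members (median log2 fold 0.38), metallothioneins for 6 of 6 (0.36) and insulin and IGF signalling genes for 9 of 13 (0.23). HIF signalling targets were lower for 21 of 26 (median -0.27), with CA9, a carbonic anhydrase that exports acid, at 18.0 and 6.07 FPKM. NF-kB targets were lower for 15 of 17 (-0.55), unfolded protein response genes for 17 of 19 (-0.43), collagen genes for 16 of 21 (-0.28) and cholesterol synthesis genes for 14 of 20 (-0.19). HIF glycolysis targets had a median of -0.18, which did not stand apart. Of 11306 genes 391 were at least 2-fold higher and 320 at least 2-fold lower, a total of 711 that became 371 with a minimum of 5 FPKM in the higher group.

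**Figure D4:**
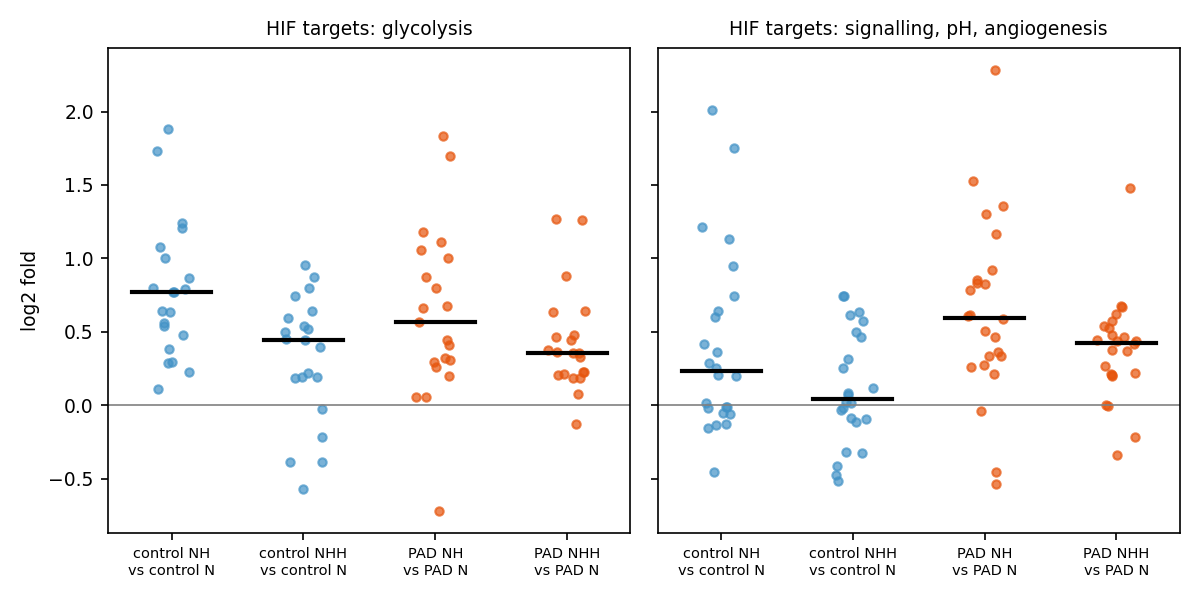
Log2 fold (vertical axis) of each measured member of the 2 lists of HIF targets in 4 comparisons of a cycled group with the N group of the same donors; points are genes and bars are medians. The glycolysis medians are 0.77, 0.44, 0.57 and 0.36 from left to right, and the signalling medians are 0.23, 0.05, 0.60 and 0.43.

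Whether PAD and control myotubes responded alike to cycling was asked by setting the log2 folds of the cycled groups side by side across genes, which are not independent replicates. Pearson's r was 0.0621 for NH over 11012 genes, with a bootstrap SD of 0.0177 over genes, and 0.0414 for NHH over 11029 genes, with a bootstrap SD of 0.0198. With at least 5 FPKM in every group, r was 0.136 for NH and 0.0063 for NHH. With the length trend removed, chosen after seeing the data, r was 0.0723 for NH and 0.0518 for NHH. The control folds come from single libraries, and no value of r for a shared response was computed. A low r therefore cannot tell unlike responses from noise. PFKFB3 stood at 17.5, 35.0 and 27.0 FPKM in PAD N, NH and NHH, and at 8.48, 31.2 and 6.48 FPKM in control. ANGPTL4 stood at 121, 83.5 and 121 FPKM in PAD and at 25.9, 87.3 and 43.3 FPKM in control. The difference between the PAD and the control response was not tested for any gene or list, because values per library were not used here.

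PAD and control were also compared within the same oxygen cycle, in contrasts added after seeing the data that do not involve control N. In PAD NH against control NH the sarcomere list had a median log2 fold of 4.22, calcium handling 4.03, myoblast markers 3.24 and myogenic regulators 3.02, and in PAD NHH against control NHH the medians were 3.52, 3.58, 2.42 and 2.53. Cholesterol synthesis genes were lower for 19 of 20 members in both (medians -0.93 and -0.90). HIF glycolysis targets (0.48 and 0.62), HIF signalling targets (0.50 and 0.73), respiratory chain subunits (0.27 and 0.23), matrix proteases (0.54 and 0.54) and TGF-beta targets (1.09 and 0.65) stood above the random lists in both contrasts. Interferon-stimulated genes (-0.57 and -0.45) and smooth muscle markers (-0.73 and -0.46) stood below them in both. NF-kB targets (0.88) and the unfolded protein response (0.35) were above and fibroblast markers (-0.47) below in the NH contrast, and metallothioneins (0.87), epithelial markers (1.32) and heat shock genes (0.39) were above and collagen genes (-0.36) below in the NHH contrast.

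The remaining lists did not stand apart in any of the 6 deposited comparisons. Their medians ran from -0.10 to 0.31 for NRF2 targets and antioxidant enzymes, 0.06 to 0.54 for mitochondrial biogenesis, -0.02 to 0.46 for fatty acid oxidation and -0.31 to 0.11 for muscle atrophy genes. They ran from 0.05 to 0.25 for autophagy, -0.14 to 0.18 for complement, -0.31 to 0.19 for immediate early genes, -0.18 to 0.44 for insulin and IGF signalling, 0.03 to 0.63 for TGF-beta targets and -0.11 to 0.39 for the unfolded protein response. Among markers of other cell types, medians ran from -0.30 to 0.08 for fibroblasts, -0.26 to 0.05 for smooth muscle and pericytes and 0.10 to 1.07 for Schwann and neural cells. Adipocyte, endothelial and immune markers and histones had fewer than 5 measured members and were not tested as lists. CIDEC, a lipid droplet protein of adipocytes, stood at 83.7 FPKM in control N and 23.6 FPKM in PAD N, the endothelial receptor KDR at 23.2 and 5.67 FPKM, the macrophage protein CD68 at 25.7 and 24.5 FPKM and the histone H2AC6 at 3.82 and 5.24 FPKM. The endothelial marker CDH5 and the epithelial marker EPCAM were listed at 0 in every group of the tables that hold them. The 37 genes of mitochondrial DNA were not tested in any table, and the highest value listed for one was 0.0793 FPKM.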

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

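Leaving out genes with scaffold copies, removing the length trend, using the primary row or the sum over copies, and matching random lists on length were chosen after the results were seen. With q under 0.01, 71 genes passed in control NH vs control N, 71 in control NHH vs control N, and 0 in each of PAD N vs control N, PAD NH vs control N and PAD NHH vs control N, where the smallest q was above 0.01. The smallest p was 5e-05 in each of these comparisons, so the smallest q depended on the authors' adjustment. The counts at q under 0.01 therefore do not compare the strength of the differences. With at least 5 FPKM in the higher group, 27 of 78 genes past q were left in PAD NH vs control N and 32 of 75 in PAD NHH vs control N. The others had under 5 FPKM in both groups. Of the 78 and 75, 54 and 45 were listed at 0 in 1 of the groups. That minimum left 497 genes at least 2-fold apart in PAD NH vs PAD N, 245 in PAD NHH vs PAD N and 371 in PAD NHH vs PAD NH, and a pseudocount of 1 left 528, 278 and 404, since the minimum removes weakly expressed genes and the pseudocount lowers their folds. Among finite folds of named genes past q, that pseudocount moved 53 by a factor of at least 1.5 and left 60 within it. Without genes with scaffold copies, 47 genes passed q in control NH vs control N, 61 in control NHH vs control N and 19 in control NHH vs control NH. Unmatched random lists left 4 lists standing apart in control NH vs control N and 5 in PAD NHH vs PAD NH, and length-matched ones left 3 in control NH vs control N; the cause was not tested. The cycling effect in PAD vs control had r = 0.136 for NH and 0.0063 for NHH with at least 5 FPKM in every group; the cause was not tested. For VARS1 in control NHH vs control NH, the log2 fold was 0.25 with the sum over copies, because its copies moved in opposite directions. After the length trend was removed, the genes past q and at least 2-fold apart numbered 106, 107, 82, 29, 78 and 75 in the 6 deposited comparisons, in the order control NH vs control N, control NHH vs control N, control NHH vs control NH, PAD N vs control N, PAD NH vs control N and PAD NHH vs control N. Genes listed at 0 in 1 of the groups have no finite fold and could not drop out when the length trend was removed. They made up 54 of the 78 in PAD NH vs control N and 45 of the 75 in PAD NHH vs control N. Not run, because values per library were not used here, were another normalization that needs per-sample counts, leaving out each PAD donor, a donor block and q thresholds between PAD groups. No paired analysis was possible because the tables used here hold 1 value per PAD group.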

Other observations

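All tests of explanations in this part were chosen after the results were seen. PAD NH stood out among the PAD groups in several genes, chosen after their values were seen. CYP4B1, a fatty acid hydroxylase, stood at 57.4 FPKM in PAD N, 0.314 FPKM in PAD NH and 24.4 FPKM in PAD NHH, and FMO2, a flavin monooxygenase, at 17.2, 0.217 and 17.1 FPKM. FRZB, a secreted Wnt antagonist, stood at 34.0, 2.16 and 21.3 FPKM, and PPP1R14A, an inhibitor of myosin phosphatase, at 640, 42.1 and 375 FPKM. The other way, the cytokine IL6 stood at 5.63, 67.5 and 12.5 FPKM, the collagenase MMP1 at 1.11, 26.8 and 3.26 FPKM, the protease inhibitor TIMP1 at 7355, 14647 and 7150 FPKM and KRT18 at 238, 1023 and 282 FPKM. In control N, NH and NHH, CYP4B1 stood at 55.2, 38.1 and 37.7 FPKM, IL6 at 0.796, 0.927 and 0.245 FPKM and FMO2, which was also lowest in NH, at 20.5, 8.98 and 20.3 FPKM. Values per library were not used here, so it is not known whether both PAD donors showed this.

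The precursor markers of muscle were low in the control groups. MYF5, an early myogenic factor, stood at 0.159, 0.185 and 0.385 FPKM in control N, NH and NHH and at 15.7, 10.3 and 16.4 FPKM in the PAD groups, and MYOD1, the myogenic master regulator, at 1.39, 2.22 and 2.31 against 32.5, 24.5 and 10.9 FPKM. The acetylcholine receptor subunit CHRNA1 stood at 17.4 FPKM in control N and 366 FPKM in PAD N, and the ryanodine receptor RYR1, the calcium release channel, at 3.94 and 35.1 FPKM. TPM2, a tropomyosin of the sarcomere list, was abundant in both cultures, at 2857 FPKM in control N and 4697 FPKM in PAD N. This 1 gene does not show how far the control culture had differentiated.

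The calls on genes with copies on extra scaffolds had 3 explanations. If reads had moved between the listed copies while their sum stayed the same, few summed values would have differed, but in control NH against control N 86.3% of the called rows of such genes still differed at least 2-fold in the sum. A response to cycling shared by control and PAD would have moved most of these genes alike in PAD NH against PAD N, but 41.8% of 55 did (Wilson 95% interval 29.7% to 55.0%). That interval treats genes as independent, although several have copies on the same scaffold. The sums of PAD N leave out copies that were not tested, which can shift the direction. Between PAD NHH and PAD NH, 34.1% of genes with copies and a mean of at least 5 FPKM differed at least 2-fold, against 3.10% of other genes of like expression, and the share was 41.0% against 3.89% between control NHH and control NH. Unstable estimates for genes whose reads also align to a scaffold copy are therefore a candidate explanation, which stays a hypothesis without the reads.

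The log2 folds against control N followed transcript length. A response to cycling shared by control and PAD would also have shown in PAD NH against PAD N, where the correlation was -0.0318. A property of the control N library may explain the trend, since PAD N against control N had a correlation of -0.288 without any cycling and the contrasts without control N lay between -0.0414 and 0.0928. Which property it was, such as fragment length or RNA quality, was not tested.

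Of 4 explanations for the higher muscle genes in PAD cultures, the length trend of control N does not account for them, since the sarcomere median was 4.22 in PAD NH against control NH, a contrast without control N. An earlier stage of the control cells within the same lineage would have left precursor markers as high in control, and the median of the myoblast and satellite cell list was 3.24. That list shares DES with the sarcomere list and PAX7, MYF5, MYOD1, CDH15 and NCAM1 with the myogenic regulators, however. Its median is therefore not separate from theirs and cannot decide on an earlier stage. A smaller share of myogenic cells in the control culture could raise muscle genes in PAD and cannot be told apart from a change within the cells: fibroblast markers (median -0.47, quartiles -0.89 and 0.21) and smooth muscle markers (quartiles -0.85 and 0.32 over the 10 with at least 1 FPKM) stood below the random lists, which goes with it, but these upper quartiles and that of the Schwann list (quartiles -0.66 and 2.24) lay above 0, and the 3 ranges overlapped. Those values are of PAD NH against control NH. Fibroblast markers did not stand apart in PAD NHH against control NHH, and neither list did in a deposited comparison. Fibroblast markers also stood below the random lists in PAD NH against PAD N. Other cell types had too few measured markers or, for epithelium, EPCAM and CDH1 under 1 FPKM, and single genes went both ways from control NH to PAD NH, with CIDEC at 119 and 7.15 FPKM, KDR at 13.0 and 0.494 FPKM and KRT18 at 72.6 and 1023 FPKM. Disease cannot be told apart from other traits of the donor or the preparation, since there was 1 control donor.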
